A study of Rattus norvegicus with 32 samples.

How the data were processed

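The series measured gene expression by sequencing polyadenylated RNA, extracted with TRIzol from livers of male Lewis rats per the labels. The labels put 12 samples before transplantation, 12 after transplantation and 8 in long-term survivors.

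The authors deposited 1 table with 32883 Ensembl rat genes and 1218 unannotated genes and 32 columns of values per library. The values are FPKM as the authors deposited them, which was worked out from the values, since the header names no unit. The submitters' processing notes list the aligner HISAT2 2.0.5 and the builds Rnor_6.0 and mm10, with no role for either build. The program that counted reads, the annotation release and the computation of FPKM are not given in the sources used here. No genome sequence was used.

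In every library, FPKM times gene length was a whole multiple of 1 step for 100% of the Ensembl genes, within 0.02 reads and for values up to 5000 reads, which gave back the read counts and the library sizes behind the values. These sizes differed from the sums of reads by scaling factors between 0.7828 and 1.4104, so the authors' values hold a scaling between libraries. In the long-term survivor columns only 3.15% to 4.987% of the values of unannotated genes were whole, and 373 of those genes were empty there, which marks a separate run with its own unannotated gene models. Only Ensembl genes were compared between groups, and 2799 of them share a symbol with another gene.

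Columns were tied to samples by their headers. A header that matches a post-transplant sample stands on 2 columns, and both were not used, since 1 of them must be another sample. A header that matches a pre-transplant sample also stands on 2 columns, which were used as pre-transplant replicates u1 and u2 with no number of their own, and 2 sample titles matched no header. Of the 32 columns, 30 were used. The plan had assumed 32 libraries with 12 pre-transplant ones, and the control libraries were therefore split into 6 and 5.

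The main test was limma 3.58.1 in R 4.3.3, with empirical Bayes (trend and robust), on log2(FPKM + 1) in 1 fit of the 3 groups, two-sided, over the 11924 genes with at least 1 FPKM in at least 8 libraries. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The 36 gene lists were tested with camera at its preset correlation of 0.01 and again with an estimated correlation, over lists with at least 3 tested members. In the text, adjusted p-values of genes are limma's, those of lists are camera's, and a ± value after a gene is its log2 fold change ± SE.

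The design, the gene lists, the rule for named genes and the first set of alternative settings were fixed before the data were examined. The rule took, per comparison, the 8 called genes with a symbol and a mean of at least 1 FPKM that had the greatest rise and the 8 with the greatest fall, up to 4 members per list with the smallest adjusted p, and the 6 leading genes per pattern of direction shared by both comparisons with pre-transplant livers. Some genes that the rule took are not reported here. The first set was a pseudocount of 0.1, no filter, median-of-ratios scaling, quantile normalization, only the groups compared, array weights, no trend and no robust fit, a fold threshold of 2, and leaving out each library in turn. Alternatives chosen after seeing the data were voom on the recovered reads, averaging of the closest long-term pairs, the same with median-of-ratios scaling, leaving out pre-transplant u1 and u2, post-transplant replicate 9 with pre-transplant u2, and long-term survivor replicates 3 and 7.

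The overlap of the comparisons with pre-transplant livers was set against 40 simulated draws of unchanged groups, and against splits of the control libraries, 10 for calls and 100 for correlations, and opposite calls against splits of the post-transplant libraries (10). Fits were tested on 5 simulated draws with 200 of the 11924 genes and a shifted list of 20 changed. Post- against pre-transplant, 51.6%, 79.7% and 93.0% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, with 4.95% false calls. Long-term survivors against pre-transplant gave 48.7%, 74.9% and 96.1% with 5.57% false calls and 1 in the wrong direction. Against post-transplant they gave 46.6%, 75.5% and 93.3% with 4.86%. In each comparison 5 of 5 shifted lists and 0 of 170 unchanged lists were called at either correlation. The data gave far more gene calls and 0 list calls at the estimated one, so the draws cannot back either.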

Results

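Gene expression was measured by sequencing polyadenylated RNA from livers of male Lewis rats, an inbred strain, in a study of liver grafts with macrosteatosis, the storage of fat in large droplets inside hepatocytes. The labels name 3 groups: 12 livers before transplantation, 12 after transplantation and 8 from long-term survivors. Of these, 11 pre-transplant, 11 post-transplant and 8 long-term survivor libraries could be tied to a group and were compared. The labels give no fat content, treatment arm, sampling time or batch, and they do not say that each library came from a separate animal, so the p-values measure the spread between these samples, which may be technical.

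Reads assigned to genes, recovered from the FPKM steps, numbered 15372950 to 19311664 in pre-transplant, 15802817 to 18464388 in post-transplant and 17401155 to 18482059 in long-term survivor libraries. The 10 most abundant genes took 18.3% to 28.6% of the reads of a library. Long-term survivor replicates 3 and 7, and 4 and 8, were far closer to each other than other libraries of a group (chi-square per degree of freedom 3.135 and 3.447, against 24.167 to 352.946 for 136 other pairs), yet differed by more than sampling noise and were kept as separate libraries. That noise covers counting error only, so that each pair may be a repeat preparation of 1 liver, and counts with the pairs averaged stand beside the comparison with pre-transplant livers. In the long-term survivor libraries, unlike the others, values of unannotated genes were not whole multiples of 1 read, which marks a separate processing run. Run and group therefore cannot be told apart, and values after rescaling by median-of-ratios factors stand beside the comparisons that include them. The median change of all genes was -0.17 in long-term survivors against pre-transplant, -0.16 against post-transplant and -0.03 post-transplant against pre-transplant. Changes are given as log2 fold changes on the log2(FPKM + 1) scale ± SE from limma, which understates the change of genes with low values.

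The first comparison asked how livers differed after and before transplantation. Post-transplant livers held more RNA of acute phase proteins, of macrophages and neutrophils, of extracellular matrix and of the cell cycle, and less RNA of hepatocyte metabolism, by list calls of which 0 held with an estimated correlation (adjusted p = 0.215 to 0.558). Lcn2, which encodes the iron-siderophore binding protein lipocalin 2, rose from 14.1 ± 21.9 to 5219 ± 3189 FPKM (SD, n = 11 and 11), a change of 8.82 ± 0.88 (adjusted p = 9.70e-09). Alb, which encodes serum albumin, fell from 49709 ± 12020.0 to 22978 ± 11975 FPKM (-1.23 ± 0.23, adjusted p = 4.87e-05). Post-transplant replicate 9 stood apart with Lcn2 at 26.9 FPKM, where the other post-transplant libraries lay between 1576 and 9473 FPKM.

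Among named genes, the 8 with the greatest rise included Lcn2 (ENSRNOG00000013973, chromosome 3, 11414186 to 11417546), Wfdc21 (ENSRNOG00000029668, chromosome 10, 71047310 to 71053191, 5.02 ± 0.32) and S100a8 (ENSRNOG00000011557, chromosome 2, 190073815 to 190074354, 4.83 ± 0.46). Others were S100a9 (ENSRNOG00000011483, chromosome 2, 190097554 to 190100276, 4.80 ± 0.41), Mt2A (ENSRNOG00000043098, chromosome 19, 11307967 to 11308740, 4.34 ± 0.61) and Lyz2 (ENSRNOG00000005825, chromosome 7, 60335969 to 60341264, 4.08 ± 0.44). The remaining ones were Orm1 (ENSRNOG00000007886, chromosome 5, 79179417 to 79182820, 4.03 ± 0.41) and Col1a1 (ENSRNOG00000003897, chromosome 10, 82745801 to 82762789, 3.80 ± 0.40). Coordinates are those of the deposited table, for which the submitters' processing notes list Rnor_6.0. S100a8 and S100a9 encode the calprotectin subunits of neutrophils and monocytes, Mt2A a metallothionein and Orm1 an acute phase glycoprotein. The highest adjusted p of these 8 was 1.49e-06 for Mt2A. The 8 with the greatest fall included Cyp2c11 (ENSRNOG00000052810, chromosome 1, 257970345 to 258004434, -5.08 ± 0.99), Ca3 (ENSRNOG00000010079, chromosome 2, 88126667 to 88135410, -4.56 ± 0.76) and Dhrs7l1 (ENSRNOG00000025648, chromosome 6, 95387718 to 95502845, -4.45 ± 0.68). Others were Ces1d (ENSRNOG00000015519, chromosome 19, 15033108 to 15239821, -3.91 ± 0.44), Stac3 (ENSRNOG00000008050, chromosome 7, 70807867 to 70815270, -3.38 ± 1.03) and Slc22a8 (ENSRNOG00000018086, chromosome 1, 224800252 to 224818482, -3.29 ± 0.53). The remaining ones were Slc13a4 (ENSRNOG00000011184, chromosome 4, 62797677 to 62840357, -3.23 ± 0.34) and Cyp8b1 (ENSRNOG00000019481, chromosome 8, 130548418 to 130550388, -3.11 ± 0.68). Adjusted p reached 0.00706 for Stac3. Cyp2c11 encodes the main male-specific cytochrome P450 of rat liver and Cyp8b1 a sterol hydroxylase of bile acid synthesis. The call of Stac3 ended with voom on the recovered reads (adjusted p = 0.0617, 0.000465 to 0.0617 over all alternatives).

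**Figure D1:**
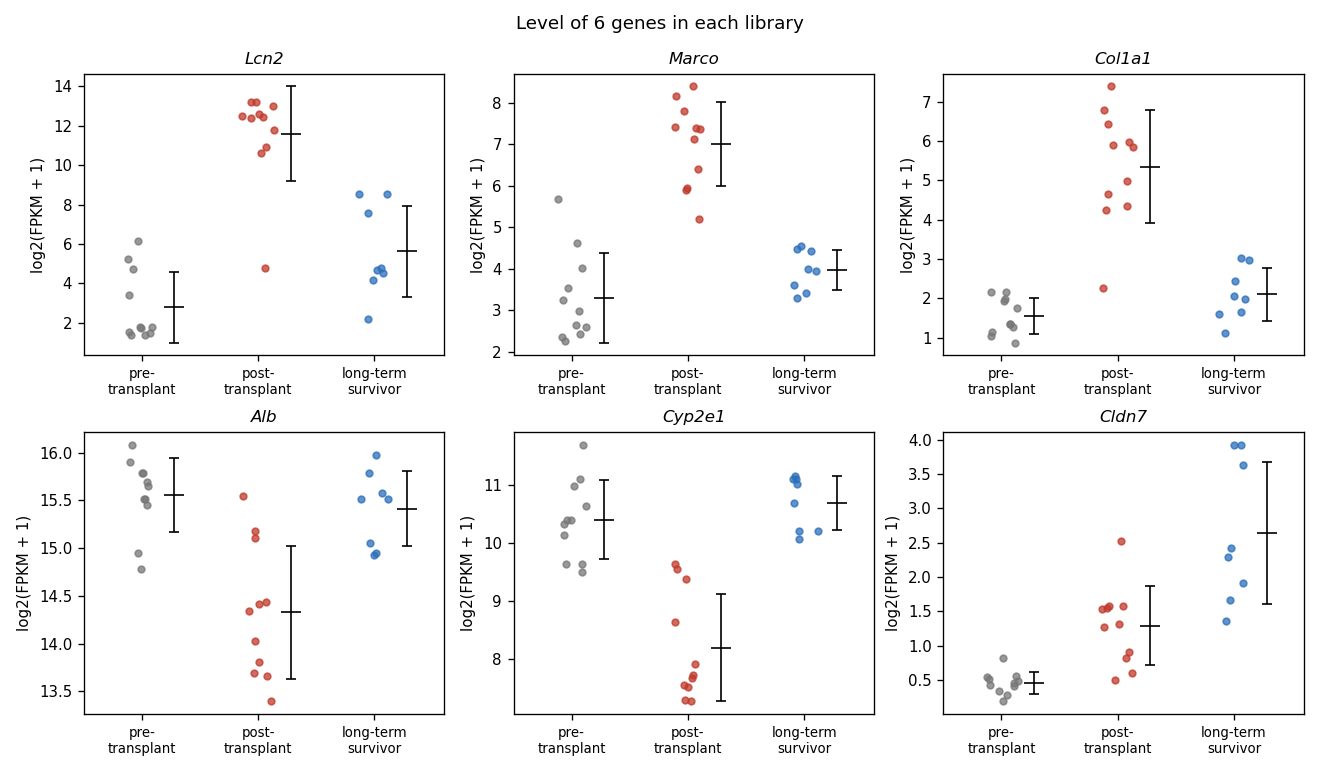
Level of Lcn2, Marco, Col1a1, Alb, Cyp2e1 and Cldn7 in each library, as log2(FPKM + 1), for 11 pre-transplant, 11 post-transplant and 8 long-term survivor libraries. Points are libraries, and the bar and whiskers beside them are the mean and SD of the log2 values.

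Matrix, macrophage, neutrophil, acute phase and cytokine lists rose. Of 28 tested extracellular matrix and stellate cell or fibroblast markers, 25 rose and 0 fell (adjusted p = 1.98e-14, adjusted p = 0.215 with an estimated correlation), among them Dcn (2.60 ± 0.22), Col4a1 (2.18 ± 0.19), Vim (2.66 ± 0.26) and Des (1.62 ± 0.15). All 16 tested monocyte and recruited macrophage markers rose (adjusted p = 6.45e-10, adjusted p = 0.215 with an estimated correlation). Examples were Cd68 (1.75 ± 0.16), Cybb (2.36 ± 0.23), Lyz2 (4.08 ± 0.44) and Tyrobp (2.09 ± 0.23). Of 13 Kupffer cell and resident macrophage markers, 11 rose and 0 fell, or 12 and 0 adjusted over the list alone (adjusted p = 4.08e-08, adjusted p = 0.215 with an estimated correlation). Examples were Marco (3.71 ± 0.38), Folr2 (2.08 ± 0.20), Csf1r (1.83 ± 0.18) and Cd5l (1.89 ± 0.20). The neutrophil markers all rose, 10 of 10 (adjusted p = 5.01e-08, adjusted p = 0.218 with an estimated correlation). An example was Ncf1 (2.91 ± 0.36), beside S100a8 and S100a9. In the list of acute phase response genes, 19 of 23 rose and 1 fell, or 20 and 1 adjusted over the list alone (adjusted p = 9.95e-10, adjusted p = 0.215 with an estimated correlation). Examples were Spink1 (3.59 ± 0.27), Kng1 (3.69 ± 0.36) and Cp (1.35 ± 0.13). For cytokines, chemokines and adhesion, 18 of 20 rose and 0 fell (adjusted p = 8.99e-09, adjusted p = 0.215 with an estimated correlation). Examples were Il1b (2.70 ± 0.31), Il10 (1.55 ± 0.17) and Icam1 (1.35 ± 0.20). Among these examples adjusted p reached 2.74e-06 for Icam1. Counts adjusted over the list alone were the same as those over all genes wherever no second count is given.

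Proliferation, interferon and regulated necrosis lists also rose. Among 29 cell cycle and proliferation genes, 26 rose and 0 fell (adjusted p = 2.14e-07, adjusted p = 0.444 with an estimated correlation). Their mean log2 level in post-transplant replicates 3, 4, 5 and 9 (1.06 to 1.60) lay within the pre-transplant range (0.88 to 2.07), and the others lay at 2.11 to 4.31. Examples were Mcm4 (1.15 ± 0.22), Mcm5 (1.77 ± 0.36) and Pcna (0.96 ± 0.20), which encode parts of the replication machinery. For interferon-stimulated genes, 17 of 28 rose and 0 fell (adjusted p = 0.000199, adjusted p = 0.469 with an estimated correlation). That level in post-transplant replicates 3, 4, 5 and 10 (2.29 to 3.36) did not exceed the pre-transplant range (2.67 to 3.502), and the others lay at 3.56 to 5.38. Examples were Oasl (1.79 ± 0.31) and Gbp2 (1.84 ± 0.38). For regulated necrosis and inflammasome, 9 of 13 rose and 0 fell (adjusted p = 0.000284, adjusted p = 0.215 with an estimated correlation). Examples were Ripk3 (1.75 ± 0.20), Casp1 (1.24 ± 0.18) and Il18 (1.29 ± 0.14). Of 17 antigen presentation genes, 14 rose and 0 fell (adjusted p = 0.000493, adjusted p = 0.444 with an estimated correlation). Examples were Psmb10 (1.16 ± 0.16) and Tap1 (0.98 ± 0.23). Among endothelial markers 8 of 19 rose and 1 fell (adjusted p = 0.00588, adjusted p = 0.457 with an estimated correlation). Examples were Esam (1.17 ± 0.12) and Cdh5 (1.04 ± 0.11). For T and NK cell markers, 5 of 12 rose and 0 fell (adjusted p = 0.0111, adjusted p = 0.457 with an estimated correlation). Examples were Cd4 (1.18 ± 0.19) and Cd8a (1.31 ± 0.30). For immediate early genes, 10 of 23 rose and 2 fell (adjusted p = 0.0316, adjusted p = 0.490 with an estimated correlation). Examples were Ccn2 (1.40 ± 0.16) and Gadd45b (2.31 ± 0.36). For hypoxia response, 9 of 17 rose and 2 fell, or 9 and 3 adjusted over the list alone (adjusted p = 0.0392, adjusted p = 0.444 with an estimated correlation). Examples were Aldoa (1.56 ± 0.21) and Hk2 (1.11 ± 0.17), which encode glycolytic enzymes. Adjusted p was at most 0.000882 among these examples, for Tap1.

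Several lists of hepatocyte function fell. Of 19 hepatocyte secreted proteins, 0 rose and 11 fell (adjusted p = 0.000608, adjusted p = 0.457 with an estimated correlation). Examples were Ttr (-2.08 ± 0.28) and Rbp4 (-1.24 ± 0.16) beside Alb. For cytochromes P450 of drug and steroid metabolism, 3 of 22 rose and 14 fell, or 4 and 14 adjusted over the list alone (adjusted p = 0.00201, adjusted p = 0.444 with an estimated correlation). An example was Cyp2e1 (-2.21 ± 0.30), the enzyme of ethanol and acetaminophen oxidation. For fatty acid oxidation and PPARA targets, 1 of 31 rose and 20 fell, or 1 and 22 adjusted over the list alone (adjusted p = 2.14e-07, adjusted p = 0.281 with an estimated correlation). Examples were Acadm (-1.80 ± 0.19) and Acaa2 (-1.42 ± 0.17). For fatty acid and triglyceride synthesis, 0 of 19 rose and 11 fell (adjusted p = 0.000874, adjusted p = 0.444 with an estimated correlation). Examples were Elovl5 (-1.79 ± 0.21) and Dgat2 (-0.89 ± 0.17). For cholesterol synthesis, 0 of 22 rose and 10 fell (adjusted p = 0.0196, adjusted p = 0.558 with an estimated correlation). Examples were Nsdhl (-1.25 ± 0.20) and Hmgcs1 (-1.26 ± 0.34). For bile acid synthesis and transport, 0 of 18 rose and 12 fell (adjusted p = 0.000340, adjusted p = 0.372 with an estimated correlation). Examples were Nr1h4 (-1.30 ± 0.17) and Slco1b2 (-1.76 ± 0.29), the bile acid receptor and a hepatocyte uptake carrier. Nuclear genes of mitochondrial oxidative phosphorylation fell in 23 of 25 cases with 0 rising (adjusted p = 5.14e-10, adjusted p = 0.272 with an estimated correlation). The list's genes are short (median 1085 bases, against 2185 for all tested genes), and after rescaling its median was -0.61, against -0.28 (middle 95% -0.59 to -0.0735) for random lists matched on length and level. Examples were Sdha (-0.95 ± 0.11), Atp5f1b (-0.79 ± 0.11) and Ndufb8 (-0.66 ± 0.09). Of 13 mitochondrially encoded genes, 0 rose and 12 fell (adjusted p = 7.62e-05, adjusted p = 0.425 with an estimated correlation). Examples were Mt-nd1 (-0.70 ± 0.15) and Mt-nd2 (-0.83 ± 0.14). Among these examples adjusted p reached 0.00266 for Hmgcs1.

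The remaining lists were not called. For NRF2 and oxidative stress, 5 rose and 10 fell of 21 (adjusted p = 0.374), and for lipid droplet and lipid uptake, 6 rose and 11 fell of 19 (adjusted p = 0.178). For urea cycle and amino acid catabolism, 1 rose and 10 fell of 18 (adjusted p = 0.0579), and for cholangiocyte markers, 5 rose and 1 fell of 10 (adjusted p = 0.0612). For p53 targets and apoptosis, 5 rose and 1 fell of 14 (adjusted p = 0.199), and for gluconeogenesis and fasting response, 1 rose and 7 fell of 17 (adjusted p = 0.265). For heat shock response, 0 rose and 4 fell of 15, 0 and 3 adjusted over the list alone (adjusted p = 0.594), and for unfolded protein response, 0 rose and 4 fell of 20, 0 and 3 adjusted over the list alone (adjusted p = 0.326). For circadian clock, 0 rose and 5 fell of 16, 0 and 4 adjusted over the list alone (adjusted p = 0.326), and for platelet and megakaryocyte markers, 2 rose and 0 fell of 3 (adjusted p = 0.0541). For B and plasma cell markers, 1 rose and 0 fell of 3 (adjusted p = 0.328), and for erythroid and blood markers, 0 rose and 0 fell of 5 (adjusted p = 0.250). For adipocyte, pancreas and gut markers, 1 rose and 1 fell of 4 (adjusted p = 0.594). In the oxidative stress list Hmox1 (2.91 ± 0.24) and Nqo1 (2.30 ± 0.31) rose and Gclc (-1.23 ± 0.16) fell, and in the lipid droplet list Fabp4 (3.31 ± 0.42) and Fabp5 (1.62 ± 0.24) rose and Hsd17b13 (-2.20 ± 0.27) fell. Further members past the test were Otc (-1.63 ± 0.26), Pf4 (2.09 ± 0.21), Jchain (1.54 ± 0.36) and Spp1 (1.91 ± 0.43). Their highest adjusted p was 0.000642 for Jchain. The heat shock list had a median of 0.0032 and a mean of -0.04, which differ in sign. The mast cell marker list had fewer than 3 tested members and was not tested.

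By limma, 5961 of 11924 genes tested passed an adjusted p of 0.05, 2787 higher and 3174 lower post-transplant, and 1261 of them changed at least 2-fold (798 higher, 463 lower). With camera's preset correlation 22 of 35 tested lists were called, 14 higher and 8 lower, and with an estimated correlation 0 were (8 at an unadjusted p under 0.05). All 11 post-transplant libraries lay past the pre-transplant range of mean levels for 4 of the 22, matrix, neutrophil, regulated necrosis and nuclear oxidative phosphorylation, and at most 5 for antigen presentation (4), fatty acid synthesis (5), cholesterol synthesis (5), endothelial markers (3) and immediate early genes (2). Calls of 3 lists rested on single libraries: immediate early genes ended without pre-transplant replicate 4 or u2 or post-transplant replicate 3 (adjusted p = 0.0514 to 0.0687), hypoxia response without pre-transplant replicate u2 (adjusted p = 0.0643) and cholesterol synthesis without post-transplant replicate 2 or 11 (adjusted p = 0.0513 and 0.0522). Other alternatives also ended them, cholesterol synthesis with quantile normalization (adjusted p = 0.211) and, with array weights, all 3 (adjusted p = 0.110 for immediate early genes, 0.0776 for hypoxia response and 0.0604 for cholesterol synthesis). Without the pre-transplant libraries u1 and u2, immediate early genes had an adjusted p of 0.120 and hypoxia response one of 0.0683. Over all alternatives adjusted p ran from 0.01004 to 0.120, from 0.00753 to 0.0776 and from 0.000831 to 0.211 for these lists. Without post-transplant replicate 9 and pre-transplant replicate u2, the libraries nearest the other group, 6284 genes were called, immediate early genes had an adjusted p of 0.0612 and hypoxia response one of 0.0576.

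**Figure D2:**
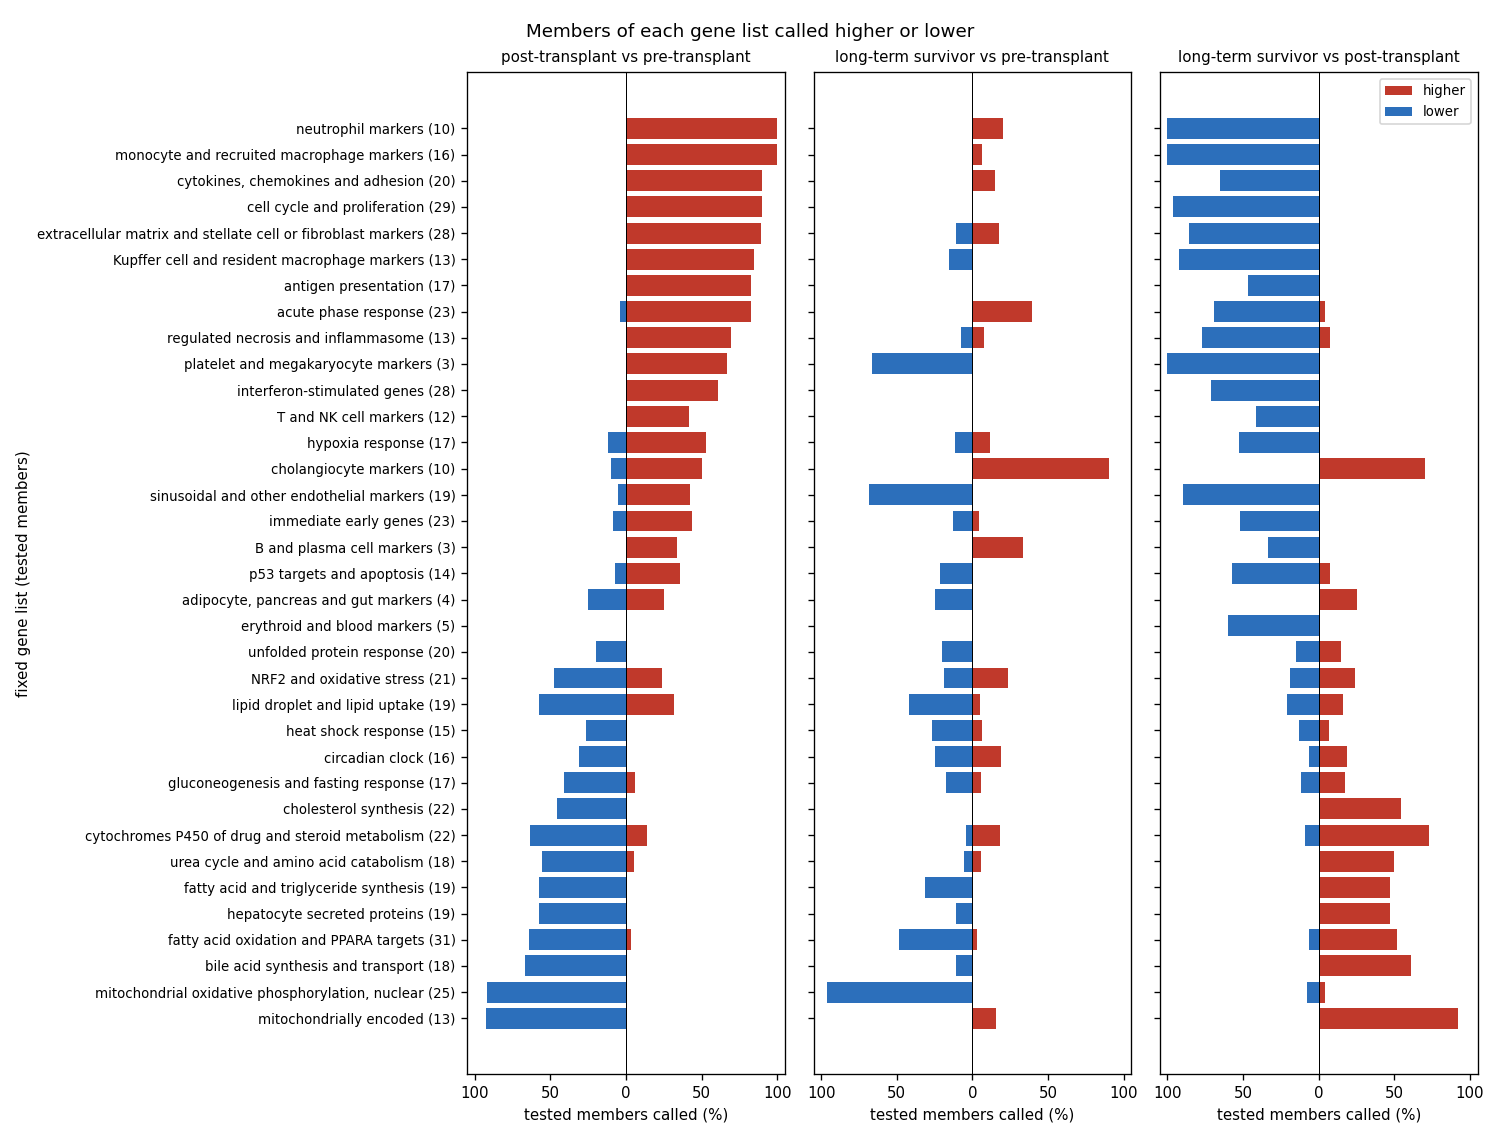
Percentage of the tested members of each gene list called higher (red, to the right) or lower (blue, to the left) at an adjusted p under 0.05 in each of the 3 comparisons. Lists are ordered by the post-transplant against pre-transplant comparison, and the number of tested members stands in parentheses.

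The second comparison asked how long-term survivor livers differed from pre-transplant ones. Long-term survivor livers held more RNA of bile duct cell markers and acute phase proteins, and less of nuclear respiratory chain genes and of sinusoidal endothelial markers, by list calls of which 0 held with an estimated correlation (adjusted p = 0.0509 to 0.524). Cldn7, a tight junction protein of epithelial cells, rose from 0.379 ± 0.162 to 6.79 ± 5.45 FPKM (SD, n = 11 and 8), a change of 2.18 ± 0.29 with a limma adjusted p of 3.19e-06. Cycs, which encodes cytochrome c, fell from 109.7 ± 18.7 to 41.8 ± 12.0 FPKM (-1.40 ± 0.15, limma adjusted p = 4.36e-07). Both calls held after rescaling, with changes of 2.32 and -1.19.

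The 8 named genes with the greatest rise included Tsx (ENSRNOG00000002925, chromosome X, 74273182 to 74283819, 3.20 ± 0.58), Lcn2 (2.86 ± 0.96) and Igh-6 (ENSRNOG00000048402, chromosome 6, 138092131 to 138093643, 2.76 ± 0.49). Others were Sds (ENSRNOG00000001388, chromosome 12, 41620393 to 41627741, 2.46 ± 0.74), Ccl21 (ENSRNOG00000034290, chromosome 5, 58197680 to 58198782, 2.43 ± 0.37) and S100a11 (ENSRNOG00000010105, chromosome 2, 193866951 to 193868502, 2.41 ± 0.38). The remaining ones were Ppp1r1b (ENSRNOG00000028404, chromosome 10, 86303727 to 86312762, 2.38 ± 0.29) and Spp1 (ENSRNOG00000043451, chromosome 14, 6673686 to 6679901, 2.37 ± 0.47). Adjusted p reached 0.0215 for Lcn2. Igh-6 encodes an immunoglobulin heavy chain, Ccl21 a chemokine of lymphatic vessels and Spp1 osteopontin. The 8 with the greatest fall included Fgf21 (ENSRNOG00000020990, chromosome 1, 101595579 to 101596822, -2.82 ± 0.45), Ndufa1 (ENSRNOG00000040005, chromosome X, 124513269 to 124516705, -2.74 ± 1.08) and Ca3 (-2.24 ± 0.83). Others were Rps29 (ENSRNOG00000028939, chromosome 13, 91334004 to 91334306, -2.05 ± 0.20), Lox (ENSRNOG00000014426, chromosome 18, 47500330 to 47577819, -1.99 ± 0.59) and AY172581.15 (ENSRNOG00000032274, chromosome MT, 3835 to 3903, -1.93 ± 0.34). The remaining ones were Nim1k (ENSRNOG00000016353, chromosome 2, 52448715 to 52492509, -1.92 ± 0.35) and Inhba (ENSRNOG00000014320, chromosome 17, 51898217 to 51912496, -1.86 ± 0.34). Adjusted p reached 0.0485 for Ndufa1. Fgf21 encodes a hormone secreted by the liver and Inhba a subunit of activin A, while AY172581.15 is a short gene of the mitochondrial genome. The values of Rps29 and Ndufa1 are uncertain too, Rps29 because ribosomal protein genes have near-identical copies. Ndufa1 swung within each group, from 0.598 to 315 FPKM pre-transplant and between near-repeat long-term survivor replicates 4 (0.828 FPKM) and 8 (78.7 FPKM).

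Of 10 tested cholangiocyte markers, 9 rose and 0 fell, 9 and 0 after rescaling (adjusted p = 2.78e-16, adjusted p = 0.0509 with an estimated correlation, 2.24e-12 after rescaling). Their mean log2 level was 3.995 and 4.044 in long-term survivor replicates 3 and 7, the closest pair, 1.87 to 3.19 in the other 6 and 1.36 to 1.94 pre-transplant, so that the lowest, replicate 2, lay within the pre-transplant range. Replicates 3 and 7 also stood apart with the lowest levels of hepatocyte secreted proteins (10.37 and 10.35, others 10.93 to 11.08) and the highest of cell cycle genes (1.89 and 1.92, others 0.81 to 1.11). Without both, 9 cholangiocyte markers rose and 0 fell (adjusted p = 4.84e-15, adjusted p = 0.0235 with an estimated correlation, 5.74e-18 to 4.53e-11 over all alternatives at the preset one). Examples were Cftr (1.43 ± 0.19), Cldn7 (2.18 ± 0.29), Cldn4 (1.36 ± 0.23) and Sox9 (1.28 ± 0.22). In the acute phase response list 9 of 23 rose and 0 fell, 11 and 0 after rescaling (adjusted p = 2.54e-10, adjusted p = 0.464 with an estimated correlation, 2.12e-07 after rescaling). Examples were Spink1 (1.91 ± 0.29), Cp (0.88 ± 0.14), Kng1 (1.90 ± 0.39) and Lbp (1.49 ± 0.35). For cytokines, chemokines and adhesion, 3 of 20 rose and 0 fell, 4 and 0 after rescaling (adjusted p = 7.70e-06, adjusted p = 0.524 with an estimated correlation, 0.00348 after rescaling). Examples were Cxcl6 (1.43 ± 0.31), Bcl3 (1.33 ± 0.31) and Cxcl16 (1.06 ± 0.30). For extracellular matrix and stellate cell or fibroblast markers, 5 of 28 rose and 3 fell, 8 and 2 after rescaling (adjusted p = 0.000199, adjusted p = 0.524 with an estimated correlation, 0.0241 after rescaling). Examples were Dcn (1.42 ± 0.24), Rgs5 (1.02 ± 0.24), Des (0.67 ± 0.16) and Vim (1.10 ± 0.28) higher. For cytochromes P450 of drug and steroid metabolism, 4 of 22 rose and 1 fell, 5 and 1 after rescaling (adjusted p = 0.000674, adjusted p = 0.524 with an estimated correlation, 0.0490 after rescaling). Examples were Cyp3a9 (1.83 ± 0.50), Cyp2c7 (1.49 ± 0.51) and Cyp2b1 (0.79 ± 0.28) higher and Cyp2b3 (-0.80 ± 0.18) lower. The list's call ended with voom (adjusted p = 0.0603, 4.63e-05 to 0.0603 over all alternatives). Of 13 mitochondrially encoded genes, 2 rose and 0 fell, or 1 and 0 adjusted over the list alone, 6 and 0 after rescaling (adjusted p = 0.000110, adjusted p = 0.524 with an estimated correlation, 0.000227 after rescaling). Examples were Mt-nd6 (0.70 ± 0.19) and Mt-nd1 (0.40 ± 0.16). Adjusted p was at most 0.0482 among these examples, for Mt-nd1. Cholesterol synthesis and antigen presentation were called upward although 0 of 22 and 0 of 17 members passed singly. Adjusted p was 0.000137 and 0.000674, 0.540 and 0.524 with an estimated correlation, and 0.00556 and 0.0241 after rescaling.

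Nuclear genes of oxidative phosphorylation fell in 24 of 25 cases and in 14 after rescaling (adjusted p = 5.46e-10, adjusted p = 0.524 with an estimated correlation, 1.73e-10 after rescaling). Short genes lay lower after rescaling, with a median of -0.18 in the shortest of 8 length classes and 0.0339 in the longest (-0.13 and 0.0092 post-transplant against pre-transplant). Examples were Cycs (-1.40 ± 0.15), Cox6a1 (-0.96 ± 0.12), Ndufb8 (-0.77 ± 0.10) and Ndufs1 (-0.75 ± 0.12). Of 19 sinusoidal and other endothelial markers, 0 rose and 13 fell, or 0 and 14 adjusted over the list alone, 0 and 10 after rescaling (adjusted p = 0.00150, adjusted p = 0.524 with an estimated correlation, 0.000287 after rescaling). Examples were Ptprb (-1.21 ± 0.19), Lyve1 (-0.97 ± 0.16), Tek (-0.69 ± 0.12) and Flt1 (-0.59 ± 0.11), all genes of endothelial receptors or surface proteins. The highest adjusted p of these 8 genes was 0.000143 for Flt1. The list of fatty acid oxidation and PPARA targets was not called (adjusted p = 0.477, adjusted p = 0.851 with an estimated correlation, 0.114 after rescaling), while 1 of 31 rose and 15 fell, or 1 and 16 adjusted over the list alone, 3 and 3 after rescaling, among them Acadvl (-0.65 ± 0.12) and Acadl (-0.47 ± 0.12). Acadl did not pass after rescaling (-0.26, adjusted p = 0.117, 0.000147 to 0.425 over all alternatives). For lipid droplet and lipid uptake, also not called (adjusted p = 0.655, adjusted p = 0.734 with an estimated correlation, 0.221 after rescaling), 1 of 19 rose and 8 fell, or 1 and 9 adjusted over the list alone, 1 and 6 after rescaling, with Mgll (-1.07 ± 0.19), Plin5 (-0.86 ± 0.17), Pparg (-0.73 ± 0.15) and Plin2 (-1.25 ± 0.27). Plin2 and Plin5 encode coat proteins of lipid droplets. In the circadian clock list, not called (adjusted p = 0.0770, adjusted p = 0.524 with an estimated correlation, 0.609 after rescaling), 3 of 16 rose and 4 fell, 3 and 1 after rescaling, with Per1 (1.01 ± 0.32) higher and Cry1 (-1.09 ± 0.24) and Arntl (-1.04 ± 0.32) lower. Arntl did not pass after rescaling (-0.87, adjusted p = 0.0612, 0.000254 to 0.156 over all alternatives), and Per1 did not without the pre-transplant libraries u1 and u2 (adjusted p = 0.0567, 0.000746 to 0.0567 over all alternatives).

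A group of 7 lists was called upward on the values as deposited and not after rescaling. They were neutrophil markers (2 of 10 rose and 0 fell, adjusted p = 0.000662, adjusted p = 0.524 with an estimated correlation, 0.0608 after rescaling), monocyte and recruited macrophage markers (1 of 16 rose and 0 fell, adjusted p = 0.000674, adjusted p = 0.524 with an estimated correlation, 0.0529 after rescaling) and Kupffer cell and resident macrophage markers (0 of 13 rose and 2 fell, adjusted p = 0.00668, adjusted p = 0.540 with an estimated correlation, 0.0608 after rescaling). The others were urea cycle and amino acid catabolism (1 of 18 rose and 1 fell, or 0 and 0 adjusted over the list alone, adjusted p = 0.00340, adjusted p = 0.540 with an estimated correlation, 0.0529 after rescaling), T and NK cell markers (0 of 12 rose and 0 fell, adjusted p = 0.00387, adjusted p = 0.524 with an estimated correlation, 0.108 after rescaling), interferon-stimulated genes (0 of 28 rose and 0 fell, adjusted p = 0.0414, adjusted p = 0.732 with an estimated correlation, 0.657 after rescaling) and regulated necrosis and inflammasome (1 of 13 rose and 1 fell, or 1 and 0 adjusted over the list alone, adjusted p = 0.0434, adjusted p = 0.524 with an estimated correlation, 0.126 after rescaling). The test ranks a list against all genes, whose median lay below 0. The interferon list was called upward with a median of -0.08 and a mean of -0.09, and the necrosis list with a median of -0.04 and a mean of 0.02. Named members past the test were S100a9 (1.56 ± 0.44, adjusted p = 0.00732), S100a8 (1.53 ± 0.50, adjusted p = 0.0181) and Cd68 (0.61 ± 0.17, adjusted p = 0.00781), and Jchain (1.50 ± 0.39, adjusted p = 0.00365) of the B and plasma cell list. Single libraries ended 2 of these calls: interferon-stimulated genes without pre-transplant replicate 3, 11 or 12, post-transplant replicate 10 or long-term survivor replicate 1 (adjusted p = 0.0508 to 0.0614), and regulated necrosis and inflammasome without pre-transplant replicates 1, 3, 4, 6, 10 or 11 or long-term survivor replicate 1 (adjusted p = 0.0507 to 0.0643). Over all alternatives the highest adjusted p was 0.0858 for neutrophil, 0.109 for monocyte, 0.101 for Kupffer cell and 0.165 for T and NK cell markers, 0.0950 for the urea cycle, 0.673 for interferon-stimulated genes and 0.275 for regulated necrosis.

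The other lists were not called. For bile acid synthesis and transport, 0 rose and 2 fell of 18, 0 and 1 adjusted over the list alone (adjusted p = 0.0770), and for gluconeogenesis and fasting response, 1 rose and 3 fell of 17, 1 and 2 adjusted over the list alone (adjusted p = 0.129). For hypoxia response, 2 rose and 2 fell of 17 (adjusted p = 0.134), and for NRF2 and oxidative stress, 5 rose and 4 fell of 21 (adjusted p = 0.134). For cell cycle and proliferation, 0 rose and 0 fell of 29 (adjusted p = 0.134), and for fatty acid and triglyceride synthesis, 0 rose and 6 fell of 19 (adjusted p = 0.154). For hepatocyte secreted proteins, 0 rose and 2 fell of 19, 0 and 1 adjusted over the list alone (adjusted p = 0.170), and for heat shock response, 1 rose and 4 fell of 15, 1 and 5 adjusted over the list alone (adjusted p = 0.183). For immediate early genes, 1 rose and 3 fell of 23 (adjusted p = 0.227), and for B and plasma cell markers, 1 rose and 0 fell of 3 (adjusted p = 0.286). For platelet and megakaryocyte markers, 0 rose and 2 fell of 3 (adjusted p = 0.497), and for p53 targets and apoptosis, 0 rose and 3 fell of 14 (adjusted p = 0.512). For erythroid and blood markers, 0 rose and 0 fell of 5 (adjusted p = 0.802), and for adipocyte, pancreas and gut markers, 0 rose and 1 fell of 4 (adjusted p = 0.857). For unfolded protein response, 0 rose and 4 fell of 20, 0 and 3 adjusted over the list alone (adjusted p = 0.938). The sign of the test differed from that of the median, the mean or both for all of these lists but platelet markers and the unfolded protein response, and for circadian clock.

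By left-out library, named by group and replicate, the call ended for Lcn2 without long-term survivor 3 or 7 (adjusted p = 0.0577 to 0.0578), for Ca3 without pre-transplant 4, 5, 6, 11, 12 or u1 or long-term survivor 3, 6 or 7 (adjusted p = 0.0522 to 0.0809), for Cyp2b1 without pre-transplant 4 or 6 or long-term survivor 2, 4, 6 or 8 (adjusted p = 0.0533 to 0.0917) and for S100a8 without long-term survivor 1 (adjusted p = 0.05001). For Mt-nd1 it ended without pre-transplant 2, 3, 4, 5, 6, 10, 11, 12, u1 or u2 or post-transplant 2, 6, 7, 8 or 10 or long-term survivor 1, 4, 5, 6 or 8 (adjusted p = 0.0505 to 0.109). For Ndufa1 it ended without pre-transplant 1, 2, 3, 5, 11 or u2 or post-transplant 2, 3, 4, 6, 8, 9, 10 or 12 or long-term survivor 1, 2, 3, 4, 5, 6 or 7 (adjusted p = 0.0504 to 0.0922). With the range over all alternatives second, averaging the near-repeat pairs ended the calls of Lcn2 (adjusted p = 0.0735, 0.000793 to 0.161), Cyp2c7 (adjusted p = 0.0502, 0.000356 to 0.0533) and S100a8 (adjusted p = 0.0513, 0.000483 to 0.201), and with rescaling added those of Cyp2b3 (adjusted p = 0.0902, 2.80e-06 to 0.0902) and Lox (adjusted p = 0.0754, 3.56e-05 to 0.179). Voom on the recovered reads ended the call of S100a9 (adjusted p = 0.105, 0.000386 to 0.105 over all alternatives), and rescaling that of Ca3 (-2.03, adjusted p = 0.0872) and Ndufa1 (-2.66, adjusted p = 0.0878). Without replicates 3 and 7 the change of Lcn2 was 1.89 (adjusted p = 0.161), and the calls of S100a8 (adjusted p = 0.0607) and Cxcl16 (adjusted p = 0.0627, 0.000109 to 0.0627 over all alternatives) ended too. Alternatives other than single left-out libraries ended the call of Ndufa1 in 11 cases (adjusted p = 0.0539 to 0.170), of Ca3 in 7 (adjusted p = 0.0592 to 0.230), of Mt-nd1 in 4 (adjusted p = 0.0636 to 0.0842) and of Cyp2b1 in 6 (adjusted p = 0.0510 to 0.108).

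By limma, 4134 of 11924 genes passed, 459 higher and 3675 lower in long-term survivors (11.1% upward). At least 2-fold changes were 282 (124 higher, 158 lower), or 162 and 72 after rescaling. After rescaling, 2136 passed, 985 higher and 1151 lower (46.1% upward), including all 459 higher and 1151 of the 3675 lower calls. With the near-repeat pairs averaged 3075 passed (287 higher, 2788 lower), and with rescaling added 1209 (558 higher, 651 lower). Without replicates 3 and 7, 3022 passed (295 higher, 2727 lower). Camera called 17 lists (15 higher, 2 lower), 10 after rescaling (8 higher, 2 lower) and 0 with an estimated correlation (2 at an unadjusted p under 0.05). Without replicates 3 and 7 it called 23 (21 higher, 2 lower), adding hepatocyte secreted proteins, fatty acid and triglyceride synthesis, bile acids, gluconeogenesis, heat shock and circadian clock upward (adjusted p = 0.0125 to 0.0471), and with an estimated correlation 1, the cholangiocyte list. All 8 long-term survivor libraries lay past the pre-transplant range for 1 of the 17 lists, nuclear oxidative phosphorylation, and 0 did for 7, cytokines, cholesterol synthesis, the urea cycle, interferon, necrosis, Kupffer cell and monocyte lists.

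The third comparison asked how long-term survivor livers differed from post-transplant ones. Long-term survivor livers held more RNA of hepatocyte metabolism and of the mitochondrial genome, and less of macrophages, neutrophils, matrix and the cell cycle, by list calls of which 0 held with an estimated correlation (adjusted p = 0.156 to 0.490). Cyp2e1 rose from 359.7 ± 254 to 1732 ± 520.4 FPKM (SD, n = 11 and 8), a change of 2.49 ± 0.33 with a limma adjusted p of 1.15e-06. Marco, a scavenger receptor of macrophages, fell from 157 ± 96.2 to 15.4 ± 5.38 FPKM (-3.05 ± 0.42, limma adjusted p = 1.69e-06). After rescaling the changes were 2.70 and -2.85.

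The 8 named genes with the greatest rise included Cyp2c11 (3.76 ± 1.08), Dhrs7l1 (3.47 ± 0.74), Ces1d (3.39 ± 0.48), Tsx (3.15 ± 0.58), Mup4 (ENSRNOG00000033130, chromosome 5, 77404914 to 77408363, 3.14 ± 0.46), Serpina6 (ENSRNOG00000009438, chromosome 6, 127523906 to 127534247, 3.09 ± 0.63) and Sdr16c6 (ENSRNOG00000040151, chromosome 5, 16972547 to 16995521, 2.91 ± 0.58), beside Pnpla3 (ENSRNOG00000022268, chromosome 7, 125034764 to 125055976, 2.74 ± 0.75). Adjusted p reached 0.00543 for Cyp2c11. Serpina6 encodes corticosteroid-binding globulin and Mup4 a major urinary protein, from a family of near-identical genes whose values are uncertain. The 8 with the greatest fall included Lcn2 (-5.96 ± 0.96), Wfdc21 (-3.58 ± 0.35), S100a8 (-3.29 ± 0.50), Col1a1 (-3.25 ± 0.44), S100a9 (-3.24 ± 0.44), A2m (ENSRNOG00000045772, chromosome 4, 154423209 to 154472924, -3.99 ± 0.49), Plac8 (ENSRNOG00000002217, chromosome 14, 10692764 to 10714524, -3.26 ± 0.44) and Gpnmb (ENSRNOG00000008816, chromosome 4, 78694447 to 78715683, -3.15 ± 0.55). Adjusted p reached 3.79e-05 for Gpnmb.

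Of 28 extracellular matrix and stellate cell or fibroblast markers, 0 rose and 24 fell, 0 and 23 after rescaling (adjusted p = 5.24e-09, adjusted p = 0.237 with an estimated correlation). Examples were Col4a1 (-2.31 ± 0.21) and Sparc (-1.52 ± 0.16). All 16 monocyte and recruited macrophage markers fell, as all did after rescaling (adjusted p = 3.00e-06, adjusted p = 0.240 with an estimated correlation). Examples were Cybb (-2.09 ± 0.25), Tyrobp (-1.85 ± 0.25) and Cd68 (-1.14 ± 0.17). For Kupffer cell and resident macrophage markers, 0 of 13 rose and 12 fell, 0 and 12 after rescaling (adjusted p = 1.07e-05, adjusted p = 0.240 with an estimated correlation). Examples were Csf1r (-1.57 ± 0.19) and Folr2 (-1.73 ± 0.21) beside Marco. For neutrophil markers, 0 of 10 rose and 10 fell, 0 and 10 after rescaling (adjusted p = 7.36e-05, adjusted p = 0.258 with an estimated correlation). Examples were Ncf1 (-2.42 ± 0.40) and Mmp9 (-2.11 ± 0.37). Among sinusoidal and other endothelial markers, 0 of 19 rose and 17 fell, or 0 and 18 adjusted over the list alone, 0 and 14 after rescaling (adjusted p = 4.08e-07, adjusted p = 0.237 with an estimated correlation). Examples were Cdh5 (-1.15 ± 0.12), Esam (-1.21 ± 0.13) and Lyve1 (-1.45 ± 0.16). For cytokines, chemokines and adhesion, 0 of 20 rose and 13 fell, or 0 and 17 adjusted over the list alone, 0 and 13 after rescaling (adjusted p = 0.00192, adjusted p = 0.369 with an estimated correlation). Examples were Il1b (-2.41 ± 0.34), Il10 (-1.35 ± 0.19) and Ccl3 (-2.12 ± 0.34). In the acute phase response list 1 of 23 rose and 16 fell, 1 and 15 after rescaling (adjusted p = 0.00593, adjusted p = 0.490 with an estimated correlation). Examples were Socs3 (-2.54 ± 0.35) and Orm1 (-2.77 ± 0.45). Among these examples adjusted p reached 3.85e-05 for Mmp9.

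Among 29 cell cycle and proliferation genes, 0 rose and 28 fell, 0 and 27 after rescaling (adjusted p = 2.32e-05, adjusted p = 0.490 with an estimated correlation). Examples were Pcna (-1.31 ± 0.22), Mcm2 (-1.48 ± 0.26) and Birc5 (-1.85 ± 0.37). For interferon-stimulated genes, 0 of 28 rose and 20 fell, 0 and 15 after rescaling (adjusted p = 0.0161, adjusted p = 0.632 with an estimated correlation). Examples were Rsad2 (-1.66 ± 0.34) and Ifit3 (-1.86 ± 0.40). The list lost its call without post-transplant replicate 9 and pre-transplant replicate u2 (adjusted p = 0.0529, 0.000113 to 0.0529 over all alternatives). For regulated necrosis and inflammasome, 1 of 13 rose and 10 fell, 1 and 8 after rescaling (adjusted p = 0.0107, adjusted p = 0.240 with an estimated correlation). Examples were Ripk3 (-1.66 ± 0.21) and Casp1 (-1.29 ± 0.20). The 3 platelet and megakaryocyte markers all fell, 2 of them after rescaling (adjusted p = 0.0107, adjusted p = 0.156 with an estimated correlation). Examples were Pf4 (-2.04 ± 0.23) and Itgb3 (-1.17 ± 0.14). Adjusted p was at most 0.000447 among these examples, for Ifit3.

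Several lists of hepatocyte function rose. For cytochromes P450 of drug and steroid metabolism, 16 of 22 rose and 2 fell, 17 and 2 after rescaling (adjusted p = 8.14e-10, adjusted p = 0.156 with an estimated correlation). An example was Cyp2b1 (1.76 ± 0.28) beside Cyp2e1. Of 19 hepatocyte secreted proteins, 9 rose and 0 fell, 13 and 0 after rescaling (adjusted p = 2.59e-07, adjusted p = 0.240 with an estimated correlation). Examples were Alb (1.09 ± 0.25), Ttr (1.48 ± 0.30) and Apoa2 (2.02 ± 0.50). For fatty acid oxidation and PPARA targets, 16 of 31 rose and 2 fell, 21 and 1 after rescaling (adjusted p = 1.12e-08, adjusted p = 0.237 with an estimated correlation). Examples were Acadm (1.05 ± 0.21) and Ehhadh (1.92 ± 0.40). For fatty acid and triglyceride synthesis, 9 of 19 rose and 0 fell, 12 and 0 after rescaling (adjusted p = 6.80e-07, adjusted p = 0.240 with an estimated correlation). Examples were Elovl5 (1.15 ± 0.23) and Fads1 (1.90 ± 0.43). For cholesterol synthesis, 12 of 22 rose and 0 fell, or 15 and 0 adjusted over the list alone, 16 and 0 after rescaling (adjusted p = 1.12e-08, adjusted p = 0.240 with an estimated correlation). An example was Nsdhl (1.22 ± 0.22). For bile acid synthesis and transport, 11 of 18 rose and 0 fell, or 13 and 0 adjusted over the list alone, 14 and 0 after rescaling (adjusted p = 1.12e-08, adjusted p = 0.156 with an estimated correlation). Examples were Akr1d1 (1.46 ± 0.26) and Slc10a1 (1.48 ± 0.34). For urea cycle and amino acid catabolism, 9 of 18 rose and 0 fell, 10 and 0 after rescaling (adjusted p = 5.79e-06, adjusted p = 0.240 with an estimated correlation). An example was Otc (1.28 ± 0.28). Among these examples adjusted p reached 0.00149 for Apoa2.

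Of 13 mitochondrially encoded genes, 12 rose and 0 fell, 13 and 0 after rescaling (adjusted p = 1.39e-12, adjusted p = 0.156 with an estimated correlation). Examples were Mt-nd1 (1.11 ± 0.16), Mt-nd2 (1.10 ± 0.16) and Mt-nd6 (1.39 ± 0.19). Among 10 cholangiocyte markers, 7 rose and 0 fell, 8 and 0 after rescaling and 3 and 0 without long-term survivor replicates 3 and 7 (adjusted p = 3.00e-06, adjusted p = 0.237 with an estimated correlation). Examples were Cftr (1.21 ± 0.19) and Cldn7 (1.35 ± 0.29). For nuclear oxidative phosphorylation genes 1 of 25 rose and 2 fell, or 0 and 1 adjusted over the list alone, 10 and 1 after rescaling (adjusted p = 0.0403, adjusted p = 0.633 with an estimated correlation). Examples were Cycs (-0.72 ± 0.15) lower and Ndufs3 (0.34 ± 0.14) higher, and the list was called upward with a median of 0.04 and a mean of -0.0014. The call of Ndufs3 (adjusted p = 0.0369) ended without post-transplant replicates 2, 3, 7, 11 or 12 or long-term survivor replicates 1, 2, 4 or 8 (adjusted p = 0.0510 to 0.0840), without a filter (adjusted p = 0.0533) and with only the groups compared in the fit (adjusted p = 0.0681). The highest adjusted p among the other examples was 0.000355 for Cycs. A group of 3 lists lost its call after rescaling: NRF2 and oxidative stress (5 of 21 rose and 4 fell, 7 and 4 after rescaling, adjusted p = 0.0403, adjusted p = 0.240 with an estimated correlation, 0.220 after rescaling), gluconeogenesis and fasting response (3 of 17 rose and 2 fell, 5 and 0 after rescaling, adjusted p = 0.00649, adjusted p = 0.240 with an estimated correlation, 0.0770 after rescaling) and circadian clock (3 of 16 rose and 1 fell, or 1 and 1 adjusted over the list alone, 3 and 0 after rescaling, adjusted p = 0.00976, adjusted p = 0.240 with an estimated correlation, 0.0929 after rescaling). In them Hmox1 (-2.14 ± 0.26) fell, and Gstm1 (1.18 ± 0.23) and Nr1d1 (1.94 ± 0.63) rose, with the highest adjusted p 0.0128 for Nr1d1. Single libraries ended the calls of NRF2 and oxidative stress (without post-transplant replicate 5 or long-term survivor replicate 3 or 7, adjusted p = 0.0541 to 0.0590, and 0.0976 without both 3 and 7) and of the oxidative phosphorylation list (without post-transplant replicate 2, 3, 11 or 12 or long-term survivor replicate 1 or 2, adjusted p = 0.0747 to 0.161). With quantile normalization the oxidative phosphorylation list pointed downward with no call (adjusted p = 0.492). Over all alternatives the highest adjusted p was 0.492 for that list, 0.685 for NRF2 and oxidative stress, 0.289 for gluconeogenesis and 0.122 for the circadian clock.

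The other lists were not called. For heat shock response, 1 rose and 2 fell of 15, 1 and 1 adjusted over the list alone (adjusted p = 0.148), and for immediate early genes, 0 rose and 12 fell of 23, 0 and 13 adjusted over the list alone (adjusted p = 0.157). For lipid droplet and lipid uptake, 3 rose and 4 fell of 19 (adjusted p = 0.193), and for hypoxia response, 0 rose and 9 fell of 17 (adjusted p = 0.196). For antigen presentation, 0 rose and 8 fell of 17 (adjusted p = 0.232), and for unfolded protein response, 3 rose and 3 fell of 20, 2 and 3 adjusted over the list alone (adjusted p = 0.274). For erythroid and blood markers, 0 rose and 3 fell of 5 (adjusted p = 0.314), and for adipocyte, pancreas and gut markers, 1 rose and 0 fell of 4, 0 and 0 adjusted over the list alone (adjusted p = 0.366). For p53 targets and apoptosis, 1 rose and 8 fell of 14 (adjusted p = 0.434), and for T and NK cell markers, 0 rose and 5 fell of 12 (adjusted p = 0.549). For B and plasma cell markers, 0 rose and 1 fell of 3 (adjusted p = 0.851). For unfolded protein response and adipocyte, pancreas and gut markers the test pointed upward with a median and mean below 0, and for lipid droplet and lipid uptake the median was 0.0005 and the mean -0.19. After rescaling immediate early genes was called downward (adjusted p = 0.0176, 0.463 with an estimated correlation, 0.006795 to 0.556 over all alternatives). By limma, 5656 of 11924 genes passed, 1255 higher and 4401 lower (22.2% upward). At least 2-fold changes were 1064 (283 higher, 781 lower), or 436 and 554 after rescaling. After rescaling 5070 passed, 2573 higher and 2497 lower (50.8% upward), including all 1255 higher and 2497 of the 4401 lower calls. Camera called 24 lists (13 higher, 11 lower), 22 after rescaling and 0 with an estimated correlation (5 at an unadjusted p under 0.05).

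In both comparisons with pre-transplant livers 2131 genes passed, 297 higher in both, 1639 lower in both, 185 higher post-transplant and lower in long-term survivors, and 10 the other way (163, 1170, 146 and 16 without long-term survivor replicates 3 and 7). Genes higher in both with the smallest p-values, with the post-transplant change first, included Unc5cl (1.16 ± 0.15 and 1.21 ± 0.16), Rtn4 (1.33 ± 0.22 and 1.60 ± 0.24), S100a11 (2.87 ± 0.35 and 2.41 ± 0.38) and Rnpepl1 (0.78 ± 0.11 and 0.76 ± 0.12), beside Spink1 and Cp. Lower in both were Ndufb8, Dynll2 (-0.71 ± 0.08 and -0.80 ± 0.09), Mpv17 (-0.85 ± 0.11 and -1.05 ± 0.12), N6amt1 (-0.51 ± 0.07 and -0.62 ± 0.08), Hsd17b10 (-1.07 ± 0.15 and -1.28 ± 0.17) and Ndufa8 (-0.82 ± 0.11 and -0.93 ± 0.12). The highest adjusted p of these, over both comparisons, was 4.23e-05 for Cp.

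Genes that rose post-transplant and stood below pre-transplant levels in long-term survivors included, in the same order of changes, Cemip2 (0.68 ± 0.12 and -0.66 ± 0.13), Ppp2r3b (0.39 ± 0.09 and -0.46 ± 0.10), Hnrnpa1 (0.57 ± 0.14 and -0.65 ± 0.15), Hpse (0.50 ± 0.11 and -0.51 ± 0.12), Bace2 (0.31 ± 0.08 and -0.38 ± 0.09) and Msr1 (0.82 ± 0.13 and -0.59 ± 0.14). The highest adjusted p was 0.00156 for Bace2 post-transplant and 0.00192 for Msr1 in long-term survivors. With that range second again, in long-term survivors Bace2 did not pass after rescaling (-0.24, adjusted p = 0.0528, 0.000104 to 0.112), Hnrnpa1 not with quantile normalization (adjusted p = 0.137, 1.24e-05 to 0.137) and Msr1 not with rescaled values and averaged pairs (adjusted p = 0.0819, 0.00106 to 0.0819), while post-transplant Bace2 did not pass with quantile normalization (adjusted p = 0.0768, 0.000515 to 0.0768). The reverse pattern held for Mt-nd6 (-0.69 ± 0.18 and 0.70 ± 0.19), Sod3 (-0.68 ± 0.17 and 0.57 ± 0.19), Prr32 (-0.80 ± 0.25 and 0.79 ± 0.27), Pdgfc (-0.44 ± 0.17 and 0.56 ± 0.18) and Cyp2b1 (-0.97 ± 0.26 and 0.79 ± 0.28). The highest adjusted p was 0.0313 for Pdgfc post-transplant and 0.0314 for Cyp2b1 in long-term survivors. The call of Pdgfc ended post-transplant without pre-transplant replicates 3, 6 or 11 or post-transplant replicates 5, 7 or 12 (adjusted p = 0.0512 to 0.0672), and in long-term survivors without long-term survivor replicate 3 (adjusted p = 0.0501). In long-term survivors that of Sod3 ended without long-term survivor replicates 3 or 7 (adjusted p = 0.0503 to 0.0505) and that of Prr32 without long-term survivor replicate 6 (adjusted p = 0.0529). There averaging the near-repeat pairs ended the calls of Sod3 (adjusted p = 0.0909, 0.00360 to 0.145 over all alternatives) and Pdgfc (adjusted p = 0.0912, 0.000610 to 0.117 over all alternatives), as did leaving out replicates 3 and 7 (Sod3 0.38, adjusted p = 0.145, and Pdgfc, adjusted p = 0.117), leaving out u1 and u2 that of Pdgfc (adjusted p = 0.0537) and a pseudocount of 0.1 that of Prr32 (adjusted p = 0.0786, 0.00742 to 0.0786 over all alternatives).

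Because both comparisons use the same pre-transplant libraries, the overlap was set against 3 references. Simulated unchanged groups, made by shuffling deviations from the group means over all libraries, gave a mean of 0 shared calls in each pattern. With no change at all hardly any gene can be called, so this 0 does not show how much overlap shared controls create. Independent lists of the same sizes would share 107.3 genes higher in both, 978.2 lower in both, 859 higher then lower and 122.2 lower then higher. With the controls split so that each comparison had its own 6 or 5, the median counts were 190.5 (128 to 311), 929 (720 to 1158), 126 and 9.5. The fold changes had r = 0.506 across genes, which are not independent replicates, against 0.417 for simulated groups (highest 0.7466) and 0.427 with split controls, and a covariance of 0.1256 against 0.0134 and 0.1094. After rescaling the 4 counts were 524, 649, 29 and 51, against 226.4, 310.5, 264.6 and 265.7 for independent lists and medians of 364.5, 364.5, 7.5 and 25.5 with split controls. Of the 2787 genes higher post-transplant, 2272 were lower in long-term survivors than post-transplant, and of the 3174 lower ones 1015 were higher. These comparisons share the post-transplant libraries, and unchanged groups gave a mean of 0 such calls, independent lists 1028.6 and 334.1, and post-transplant libraries split between the comparisons medians of 1596.5 (1508 to 1648) and 698.5 (401 to 755). After rescaling the counts were 1798 of 2741 and 1803 of 3217, against 574 and 694.2 for independent lists. With the split the medians were 1170 and 1010, where medians of 2274.5 and 2538.5 genes were called.

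**Figure D3:**
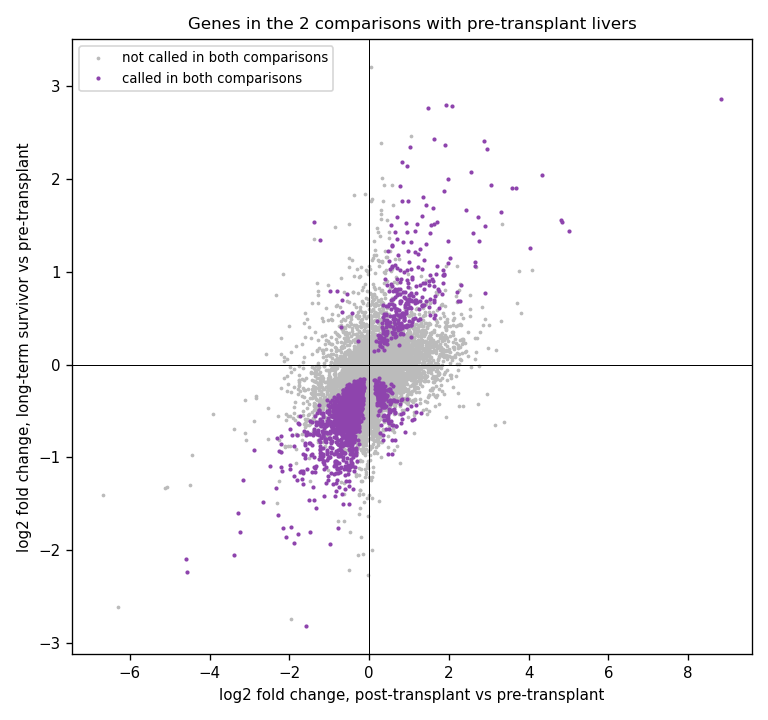
Log2 fold change of each of 11924 tested genes post-transplant against pre-transplant (horizontal axis) and in long-term survivors against pre-transplant (vertical axis), on the log2(FPKM + 1) scale. The 2131 genes called in both comparisons are purple, and all other tested genes are grey.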

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

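The tests of short transcripts, of scaling, of separate processing, of the hepatocyte share, of a wrong label and of outliers with averaged pairs were chosen after the results were seen, and the 3 counts of other splits were planned. Among 168 values tested in the 8 long-term survivor libraries, 11 had 1 library far from the others, where chance alone gives about 1 in 20 among independent libraries. Long-term survivor replicate 1 stood apart for Igh-6 (95.9 FPKM, nearest 23.9), Hmox1 (85.3, nearest 32.8), Il1b (8.80, nearest 5.28) and A2m (4.20, nearest 0.708). Replicate 2 stood apart for Dynll2 (72.9 FPKM, nearest 61.7) and Nim1k (0.902, nearest 0.419), and replicate 8 for Ndufa1 (78.7, nearest 0.828). Replicate 3 did for AY172581.15 (0.692, very few reads, with the others at 0). Replicate 6 stood apart for Lox (2.31 FPKM, nearest 0.586), Rsad2 (0.293, nearest 0.499) and the mean log2 level of the Kupffer cell and resident macrophage list (4.42, nearest 4.62). Near-repeat replicates 3 and 7, and 4 and 8, hide a shift that both share. With each pair averaged, 15 of the 168 values had 1 of the 6 far from the others, 10 of them the pair 3 and 7, on the log2 scale among them Cyp2c11 (2.65, nearest 8.20), the secreted protein list (10.36, nearest 10.93), the cell cycle list (1.91, nearest 1.11) and the matrix list (2.90, nearest 2.55). Among 544 unannotated genes tested outside the main comparison, 59 were higher and 199 lower post-transplant than pre-transplant by limma.

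Of 100 splits of the libraries, 1, the real one, reached the real count in each comparison, with limma fits of the groups compared. There were 5691 genes post-transplant against pre-transplant (highest other 1565), and 4817 (812) and 5305 (1) in long-term survivors against pre- and post-transplant. This argues against chance only for independent libraries. Near-repeat pairs may not be, and labels name no animal.

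Nuclear oxidative phosphorylation genes were lower in long-term survivors than pre-transplant. They are short. After rescaling their median change of -0.3759 lay below the middle 95% of random lists matched on length and level (-0.262 to 0.0031, median -0.1338). If genes vary independently, this argues against a lower yield of short transcripts as the whole cause, though not a part. With an estimated correlation camera gave the rescaled list an adjusted p of 0.744. The median was -0.5813 as deposited and -0.3489 (bootstrap interval -0.4999 to -0.1736) after rescaling with the pairs averaged. This argues against scaling between the runs as the whole cause, though not a part. Separate processing of the long-term survivor libraries stays open, as 0 groups have libraries in both runs, as does a difference between the groups.

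Post-transplant livers had less RNA of hepatocyte genes and more of other cell types. A lower share of hepatocyte RNA alone would raise the markers of other cell types alike, but the monocyte and macrophage list rose by 1.5383 more than the endothelial list on the mean log2 scale (bootstrap interval 1.0424 to 2.036). An influx of macrophages, with or without a change in hepatocytes, may explain the pattern, and this was not tested.

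Post-transplant replicate 9 lay close to the pre-transplant libraries in acute phase genes. Its mean log2 level of the acute phase list, 8.28, lay within the pre-transplant range (7.67 to 8.31, other post-transplant libraries 9.34 to 10.6), and on an axis from pre-transplant (median -0.068) to post-transplant (median 1.0987), from genes called without it, its position of 0.3657 lay above all pre-transplant libraries (-0.2028 to 0.3054) except u2 (0.4717). Its matrix list stood at 4.02, against 2.25 to 2.70 pre-transplant and 2.53 to 2.91 in long-term survivors, and its Col1a1 at 84.8 FPKM, against at most 3.45 FPKM pre-transplant. For the matrix list that is 8.7488 SDs from the pre-transplant libraries, while no pre-transplant library lay more than 4.6145 SDs from the others in any list, which argues against a pre-transplant library under a post-transplant label. A sample from outside the series and a graft with a small acute phase response stay open, as neither was tested.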

How the results depend on the processing

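The alternatives with voom, with averaged pairs and without 2 libraries at once were chosen after seeing the data. No named gene reversed, and no list was called in opposite directions (0). The test pointed the other way, with no call there, for 1 called list, nuclear oxidative phosphorylation in long-term survivors against post-transplant with quantile normalization (adjusted p = 0.4917), and for lists not called. In long-term survivors against pre-transplant these were cell cycle, erythroid, and adipocyte, pancreas and gut lists with median-of-ratios scaling (0.7177, 0.7185 and 0.7177), quantile normalization (0.6238, 0.7099 and 0.7099), voom (0.6729, 0.8919 and 0.6729) and averaged pairs with rescaling (0.5634, 0.8039 and 0.7221). There too were the erythroid list without u1 and u2 (0.516), without replicate 9 and u2 (0.6644) and without u2 (0.7431, in a range of 0.551 to 0.9326 over left-out libraries), immediate early genes with voom (0.9447) and averaged pairs with rescaling (0.8054), p53 targets without a filter (0.9588), and the unfolded protein response with averaged pairs (0.832), without replicates 3 and 7 (0.5841) and without pre-transplant replicate 3, 4, 5 or 10 or long-term survivor replicate 3 or 7 (0.7971 to 0.9993). Post-transplant against pre-transplant they were heat shock and unfolded protein response with quantile normalization (0.3676 and 0.5229) and the adipocyte, pancreas and gut list without a filter (0.63), and in long-term survivors against post-transplant the unfolded protein response with quantile normalization (0.5293) and B and plasma cells without long-term survivor replicate 6 (0.985, in a range from 0.5954 over left-out libraries). The cause of these changes was not tested. With a fold threshold of 2, 1261 genes changed post-transplant against pre-transplant, 282 in long-term survivors against pre-transplant and 1064 in long-term survivors against post-transplant, as that threshold removes smaller changes. In long-term survivors against pre-transplant, median-of-ratios scaling gave 2136 genes, 10 lists and 1253 genes changed in both groups, in place of 4134, 17 and 2131. Voom gave 1984 genes, 10 lists and 1167 in both, quantile normalization 1979 genes and 1132 in both, averaged pairs with rescaling 1209 genes, 10 lists and 711 in both, and array weights 3280 in both. Scaling, quantile normalization and voom brought the median change of all genes in long-term survivors against pre-transplant from -0.17 to between -0.0143 and 0.002, and beyond that the cause was not tested.

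Other alternatives gave 5691 to 7377 genes and 19 to 26 lists post-transplant against pre-transplant, 1209 to 5961 and 10 to 23 in long-term survivors against pre-transplant, and 4498 to 6793 and 22 to 25 against post-transplant. Leaving out each library in turn gave 5484 to 6151 genes and 21 to 24 lists, 3574 to 4243 and 15 to 19, and 5237 to 5815 and 23 to 24 in these comparisons, with 1804 to 2260 genes changed in both groups. Of the named genes, 98 (all but 3), 56 of 76 and 68 of 69 kept direction and call under every alternative run in the comparisons in the same order, and of 35 lists 25, 14 and 25 did. With an estimated correlation 1 list was called in long-term survivors against pre-transplant at a pseudocount of 0.1, with averaged pairs, without long-term survivor replicates 3 and 7 together, and without post-transplant replicate 2 or long-term survivor replicate 1, 2, 3 or 7. At this depth the limit taken of 3 reads is 0.119 to 0.235 FPKM in a gene of 1 kb. It is lower in longer and higher in shorter genes. No paired analysis was possible because the replicate numbers only name samples and the labels pair none.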

Other observations

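Among post-transplant libraries (n = 11), the level of the monocyte and macrophage list was set against 4 hepatocyte lists, a test planned with its criterion before the result was seen, while the pre-transplant values and the reading of its outcome as open came after. Post-transplant, the secreted protein list fell as the macrophage list rose (Pearson r = -0.8901, permutation p = 4e-04, adjusted p = 8e-04; Spearman rho = -0.8364, permutation p = 0.00237, adjusted p = 0.00776), with r = -0.7223 without the 2 farthest libraries. So did the cytochrome P450 list (r = -0.9005, permutation p = 0.00011, adjusted p = 0.00044; rho = -0.8091, permutation p = 0.00388, adjusted p = 0.00776), with r = -0.8289 without them. The oxidative phosphorylation and fatty acid oxidation lists had r = -0.5276 and -0.4486 (permutation p = 0.0945 and 0.167, adjusted p = 0.126 and 0.167; rho = -0.4364 and -0.4545, permutation p = 0.182 and 0.163, adjusted p = 0.182 for both), with r = -0.4889 and -0.3344 without the 2 farthest.

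The criterion, an adjusted p under 0.05 for all 4 lists, was not met, since 2 of the 4 passed. A shared gradient across all 4 lists is left open rather than excluded because at n = 11 a p that misses the threshold does not show that there is no relation, and the bootstrap intervals of r for the other lists lay below 0 (-0.8343 to -0.1515 and -0.773 to -0.0146). Among pre-transplant libraries (n = 11) the secreted protein list also fell as the macrophage list rose (r = -0.8693, permutation p = 2e-04, adjusted p = 8e-04; rho = -0.8545, permutation p = 0.00156, adjusted p = 0.00624), with r = -0.6896 without the 2 farthest. There the P450, fatty acid oxidation and oxidative phosphorylation lists had r = -0.3686, 0.2498 and 0.131 (permutation p = 0.274, 0.456 and 0.708, adjusted p = 0.548, 0.608 and 0.708), rho = -0.1455, 0.1818 and -0.1545 (permutation p = 0.674, 0.594 and 0.653, adjusted p = 0.674 for each), and r = 0.57, 0.4867 and 0.4007 without the 2 farthest. A gradient of response between grafts may lie behind the post-transplant relations, and no label allowed a test of what sets it.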
